A study of Homo sapiens with 8 samples.

How the data were processed

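The data are 8 tables of gene expression from RNA sequencing of the cell lines MCF7 and HCT116, each treated with Akti-1/2 or DMSO, with 2 libraries in each of the 4 groups. Per the labels' protocols, libraries were made from 4 µg of total RNA with the TruSeq RNA v2 kit and marked the strand with dUTP in the second strand. Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.25, aligned to hg19 with TopHat2 2.0.8b and Bowtie2 2.1.0, and turned into gene values with Cufflinks 2.1.1. The notes are not clear on which of the versions 2.0.8b and 2.1.1 belongs to Cufflinks, and this pairing is a reading made here. The deposited values are FPKM, with an interval and a status for each gene, per the file headers. The sources used here do not give the annotation, whether the quantification used the strand, or any count of fragments, so no count-based model was fitted and the depth of each library is unknown. In place of depth, the precision of a gene was read from the deposited intervals: the median of the squared ratio of FPKM to its standard error was 138 to 402 per library.

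Each table holds 24934 entries for 23284 gene names. Entries that share a name (543 names) were summed, and 196 names without an OK status in every sample were left out. A gene was tested if its mean reached 1 FPKM in at least 1 group, which left 13049 genes. Values were compared as log2(FPKM + 1), without further scaling, in 1 linear model over all 8 samples (limma 3.58.1 in R 4.3.3, empirical Bayes with trend and robust settings, 4 residual degrees of freedom). The contrasts were inhibitor minus vehicle in each line, and the MCF7 effect minus the HCT116 effect. P-values were adjusted by Benjamini-Hochberg within each contrast, with a threshold of 0.05. The groups share no control libraries.

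Gene groups were 36 lists written by hand from general knowledge before the data were examined, of which 35 had at least 5 tested genes. The list of stromal, endothelial and blood cell markers had 4 and was not tested; of these 0 rose and 3 fell in MCF7, and 0 rose and 2 fell in HCT116. Lists were tested with camera, which asks whether a list moves relative to all other genes, with the preset correlation between genes of 0.01. Its direction can thus differ from the sign of a list's own median. Alternatives were camera with the correlation estimated for each list, and fry, which asks whether a list moves one way and makes no comparison with other genes. Each list was also counted with p-values adjusted over the list alone.

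Genes were named by a rule fixed before the data were examined. It took, for each line, the 8 rising and 8 falling genes with the largest change that passed the test, had both inhibitor samples on the same side of both vehicle samples, and reached 5 FPKM in the higher group. It added up to 4 members of each list and line with the smallest adjusted p, and 8 genes per direction changed in both lines. It also took 6 per direction with the smallest adjusted p in the line difference, and 18 fixed genes of the pathway and the lines. AKT3 and IGF1 were among the fixed genes and stayed under 1 FPKM.

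Same-numbered libraries of different groups deviated together: the correlation of their replicate differences was 0.46 to 0.67 in all 6 pairs of groups, so the numbers pair the samples in the data, while the labels give no reason for it. The model has no block for the replicate number, and a fit with that block was an alternative. Within groups, replicates correlated with Pearson's r of 0.990 to 0.994. Other alternatives written before the data were examined were a pseudocount of 0.1, no FPKM filter or a filter of 5, median-of-ratios scaling, quantile normalization, scaling to an equal total (TPM scale), each line on its own, no trend or robust setting, all genes whatever their status, genes with several entries left out, a 2-fold limit, and each library left out in turn.

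Alternatives added after the data were seen dealt with GC content, small RNAs and a common block for the replicate number. GC content and length came from the longest protein-coding transcript of each gene name in GENCODE v29, otherwise its longest transcript, while coordinates are those of the files. For the GC-adjusted values, a loess curve of each library's deviation from the gene mean on GC content and mean level (span 0.3) was subtracted. A further setting kept only genes under 48% GC. Small RNAs (1581 names spanning less than 200 bp) were left out of these fits, and in other settings left out of the test or of the total used for scaling. The code was tested on simulated data with known changes. Without a GC trend, 93% of genes changed by 1 on the log2 scale were found in each line, and 0.08% of unchanged genes were called. Changes were placed only in genes above 5 FPKM in the vehicle libraries of both lines, so the 93% does not cover weakly expressed genes. Scripts ran in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.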

Results

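RNA sequencing measured gene expression in 2 established human cancer cell lines treated for 72 h with the AKT inhibitor Akti-1/2 or with its solvent, DMSO. MCF7 is an oestrogen receptor-positive breast adenocarcinoma line and HCT116 is a colorectal carcinoma line. Akti-1/2 is an allosteric inhibitor of the kinases AKT1 and AKT2, which carry signals from growth factor receptors and PI3K to growth, survival and metabolism. MCF7 cells received 2 µM and HCT116 cells 20 µM, so differences between the lines cannot be separated from the dose. Each of the 4 groups had 2 libraries, and 13049 genes entered the tests. Between 9576 and 12079 genes per library reached 1 FPKM (fragments per kilobase of transcript per 1000000 mapped fragments). The tables give no fragment counts, so the depth of each library is unknown. The records do not say that the 2 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. The libraries carried a gene that marks each line. ESR1, the oestrogen receptor, was at 37.0 ± 0.469 FPKM (SD, n = 2) in MCF7 vehicle libraries. CDX2, an intestinal transcription factor, was at 6.38 ± 0.534 FPKM (SD, n = 2) in HCT116 vehicle libraries. Of the written marker lists, 21 of 22 luminal breast markers but only 6 of 24 colon epithelial markers entered the tests.

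The inhibitor libraries of both lines were lower in transcripts rich in G and C, a property that moved with treatment and is given beside the gene groups it touches. In the 1245 genes with the highest GC content, 62 to 74.1%, the median change was 1.78-fold lower in MCF7 and 8.7-fold lower in HCT116. Of these genes, 69.7% fell in MCF7 and 97.3% in HCT116. Over 12448 genes with a GC value, Spearman's rho between log2 fold change and GC content was -0.591 in MCF7 and -0.73 in HCT116, across genes, which are not independent replicates. Values called GC-adjusted come from libraries with this trend, and any trend with mean level, subtracted, an addition made after the data were seen. The adjustment can also move genes that are not expressed. CST6, a cystatin at 0 FPKM in all MCF7 libraries, was called higher there when GC-adjusted (log2 fold change 1.06, limma adjusted p = 0.000144). Counts of GC-adjusted calls include such genes. Simulated data carried a smooth GC trend fitted to these data and weakened in lowly expressed genes. There, unadjusted values gave false calls for 63.2% of unchanged genes in MCF7 and 53% in HCT116. Adjusted values gave false calls for 4.08% and 23.3%, and for 13.1% in the line difference. The simulation had independent noise and few changed genes, so these rates need not hold for the data.

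**Figure D1:**
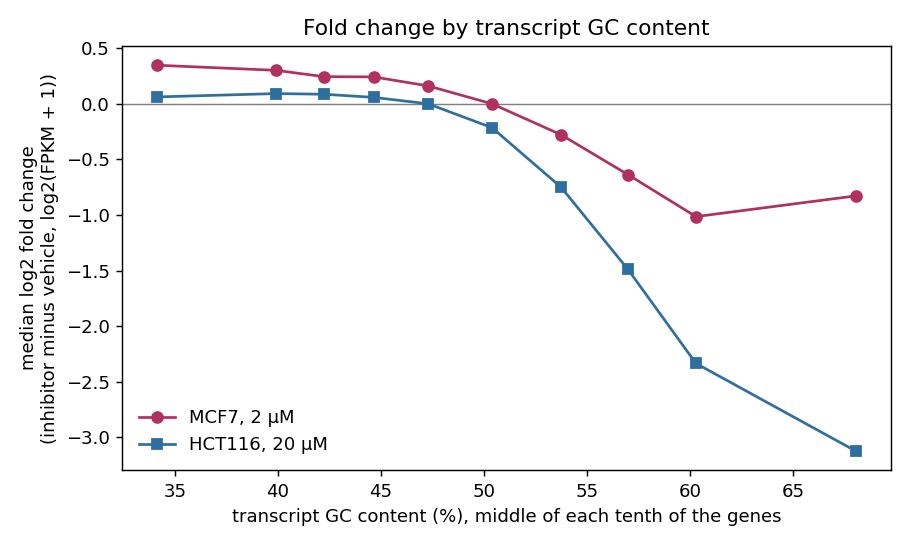
Median log2 fold change (inhibitor minus vehicle, on the log2(FPKM + 1) scale) against transcript GC content in percent, 1 point for each 10% of the 12448 genes, for MCF7 at 2 µM (circles) and HCT116 at 20 µM (squares). The 1245 genes richest in GC lie at -0.83 in MCF7 and -3.12 in HCT116.

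The first comparison asked which transcripts differ in MCF7 cells when AKT is inhibited. Genes of DNA replication and entry into S phase were higher with the inhibitor. GINS2, a subunit of the replicative helicase (hg19 chromosome 16, 85711280 to 85722588), was at 6.41 ± 0.202 FPKM in vehicle and 83.3 ± 1.11 FPKM in inhibitor libraries (SD, n = 2 each), 11.4-fold higher (log2 fold change 3.51, SE 0.03, limma adjusted p = 2.14e-07). MCM6, another helicase subunit (chromosome 2, 136597196 to 136634011), rose 5.84-fold from 9.63 ± 0.218 to 61.0 ± 0.341 FPKM (SD, n = 2 each). CCNE2 (cyclin E2), RRM2 (a ribonucleotide reductase subunit) and CDC6 (which loads the helicase onto origins) rose 11.1-fold, 10.6-fold and 5.07-fold. Of 36 measured DNA replication and G1/S genes, 32 rose and 3 fell, the same numbers when adjusted over the list alone, with a median log2 fold change of 1.47. The set test camera gave adjusted p = 2e-08 with its preset correlation and adjusted p = 0.214 with an estimated correlation. GC-adjusted, 34 rose and 1 fell with a median of 1.63 (camera adjusted p = 4.5e-11). Folds are ratios on the log2(FPKM + 1) scale and understate changes of weakly expressed genes.

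G2/M and mitosis genes rose with them. CCNB2 (cyclin B2) rose 2.58-fold, CCNA2 (cyclin A2) 2.46-fold, ANLN (the cytokinesis scaffold anillin) 2.06-fold and MKI67, the Ki-67 proliferation marker, 1.88-fold, from 14.1 ± 0.369 to 27.4 ± 0.0822 FPKM (SD, n = 2 each). Of 36 measured, 23 rose and 8 fell, also when adjusted over the list alone (camera adjusted p = 0.0143, adjusted p = 0.602 with an estimated correlation). The list median was 0.48. The call ended when GC-adjusted (adjusted p = 0.15, median 0.29), with quantile normalization (0.177, median 0.53), on the TPM scale (0.112, median 0.20) and under 48% GC (0.373, median 0.55), and the medians with quantile normalization and under 48% GC were no smaller. CDKN1B, the CDK inhibitor p27, stood at 46.2 ± 4.24 FPKM with inhibitor and 40.1 ± 4.54 with vehicle (SD, n = 2 each); the CDKN1B MCF7 log2 fold change was 0.20 (limma adjusted p = 0.0882, and 0.00594 with the replicate number as a block). The replication-dependent histone genes went the other way: 16 of 18 fell and 0 rose, also when adjusted over the list alone, with a median of -1.27 (camera adjusted p = 0.000383, adjusted p = 0.308 with an estimated correlation). HIST1H2BD fell 1.95-fold and HIST2H4A 25.4-fold. Most of these messages lack a poly(A) tail, which the library kit normally selects for, and GC-adjusted the list median was -1.40 (adjusted p = 0.000704).

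Stress and p53 target genes were lower in inhibitor-treated MCF7 cells. Of 27 measured targets of ATF4, the transcription factor of the amino acid response, 24 fell and 2 rose, also when adjusted over the list alone, with a median of -1.95 (camera adjusted p = 2.21e-07, adjusted p = 0.214 with an estimated correlation). ASNS (asparagine synthetase; chromosome 7, 97481429 to 97501854) fell 5.72-fold, from 275 ± 8.38 to 47.2 ± 0.503 FPKM (SD, n = 2 each; log2 fold change -2.52, SE 0.04, limma adjusted p = 5.51e-07). SLC7A11, the cystine transporter subunit, fell 6.9-fold, WARS (tryptophanyl-tRNA synthetase) 5.95-fold and NUPR1, a stress-induced nuclear protein, 103-fold. Of 30 p53 targets 25 fell and 2 rose, or 26 and 2 when adjusted over the list alone, with a median of -0.80 (camera adjusted p = 1.46e-05, adjusted p = 0.214 with an estimated correlation). TNFRSF10B (death receptor 5) fell 3.66-fold, XPC (a DNA damage sensor) 2.20-fold and CDKN1A (the CDK inhibitor p21) 8.27-fold. Of 20 ER chaperone genes 17 fell and 2 rose, also when adjusted over the list alone, among them HSPA5 (the chaperone BiP) 2.25-fold and HERPUD1 1.99-fold (median -0.78, camera adjusted p = 0.000383, adjusted p = 0.308 with an estimated correlation and 0.262 on the TPM scale, where the median was -1.09). GC-adjusted medians were -1.24 for ATF4 targets (camera adjusted p = 2.66e-07), -0.80 for p53 targets (1.28e-05) and -0.90 for ER chaperones (0.000171).

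Oestrogen receptor targets rose as a group in MCF7. Of 26 measured, 20 rose and 4 fell, also when adjusted over the list alone, with a median of 0.41 (camera adjusted p = 0.00405, adjusted p = 0.262 with an estimated correlation). PDZK1, a scaffold protein induced by oestrogen, rose 8.33-fold, CA12 (carbonic anhydrase 12) 2.91-fold, CCND1 (cyclin D1) 2.72-fold, ELOVL2 (a fatty acid elongase) 2.25-fold and ESR1 itself 2.01-fold to 75.3 ± 0.0971 FPKM (SD, n = 2). TFF1, a secreted trefoil peptide and oestrogen target (chromosome 21, 43782391 to 43786644), fell 24.6-fold, from 2002 ± 305 to 80.5 ± 12.1 FPKM (SD, n = 2 each; limma adjusted p = 1.49e-06). GC-adjusted the group median was 0.86 (camera adjusted p = 0.00898), while the call ended with quantile normalization (adjusted p = 0.0927), where the median was 0.54, and on the TPM scale (0.262), where it was 0.09. Under 48% GC 9 of 9 measured genes rose (median 1.17, adjusted p = 0.0231, and 0.0507 with the replicate block). In HCT116, 4 genes of the list rose, 11 fell and 11 did not pass as deposited (median -0.01). GC-adjusted, 19 rose and 3 fell there (median 0.40, camera adjusted p = 0.146), but the adjustment can also move genes that are not expressed. Under 48% GC, 3 of 9 rose and 1 fell in HCT116 (median 0). The list did not pass in the line difference (camera adjusted p = 0.274, 0.457 when GC-adjusted and 0.157 under 48% GC). It passed there with quantile normalization (adjusted p = 0.0379, median 0.61) and without an FPKM filter (0.0473).

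The list of PI3K-AKT-mTOR pathway members did not pass the test in MCF7: of 34 measured 11 rose and 16 fell, also when adjusted over the list alone, with a median of -0.10 (camera adjusted p = 0.484, adjusted p = 0.937 with an estimated correlation; GC-adjusted median -0.02). AKT1 (chromosome 14, 105235687 to 105262080), one of the inhibitor's targets, fell 5.97-fold from 67.7 ± 13.4 to 10.5 ± 2.13 FPKM (SD, n = 2 each; log2 fold change -2.58, -1.41 when GC-adjusted) and AKT2 fell 6.84-fold (-2.77, -1.59 when GC-adjusted). AKT3 was at or below 0.0506 FPKM in the MCF7 libraries and was not tested. PIK3R1, the regulatory subunit of PI3K, rose 2.59-fold, and ERBB3, a receptor of the EGFR family, rose 1.44-fold. Of 28 measured FOXO targets, the genes of transcription factors that AKT restrains, 10 rose and 11 fell, also when adjusted over the list alone (camera adjusted p = 0.957). BCL2L11 (the pro-apoptotic protein BIM) fell 2.50-fold and TXNIP, a glucose-responsive inhibitor of thioredoxin, fell 2.26-fold. The insulin pathway adaptor IRS2 (log2 fold change 0.04, limma adjusted p = 0.59; 1.32 and 3.29e-05 when GC-adjusted) and the receptor IGF1R (0.06, adjusted p = 0.133; 0.31 and 9.5e-05 when GC-adjusted) did not pass the test. INSR, the insulin receptor, was at -0.11 (adjusted p = 0.0286), and at 0.13 with quantile normalization, and lost its call without any of 3 of the 4 MCF7 libraries.

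Cytosolic ribosomal protein genes and epithelial genes passed the test in MCF7 only before adjustment for GC. Of 58 ribosomal protein genes 32 fell and 11 rose, also when adjusted over the list alone (median -0.66, camera adjusted p = 0.0197, adjusted p = 0.872 with an estimated correlation, 0.15 when GC-adjusted). RPL8 fell 30.1-fold and RPS28 44.2-fold, and within the list the 18 genes with at least 55% GC had a median of -3.53 against 0.19 for the 20 genes under 48% GC. Of 24 epithelial genes 15 fell and 4 rose, also when adjusted over the list alone, among them KRT19 (keratin 19) 16.4-fold and JUP (plakoglobin) 15.3-fold (camera adjusted p = 0.0331, adjusted p = 0.602 with an estimated correlation, 0.179 when GC-adjusted). Without MCF7 vehicle replicate 1 the epithelial call was lost (adjusted p = 0.0574).

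In all, 4798 genes rose and 4837 fell in MCF7 (limma, Benjamini-Hochberg adjusted p under 0.05), and 557 rose and 2073 fell at least 2-fold. CAV1 (caveolin-1, the coat protein of caveolae) rose 14.9-fold from 7.24 ± 0.13 to 121.9 ± 1.14 FPKM (SD, n = 2 each), and FAM111B rose 12.2-fold. Several of the largest changes were of small nucleolar RNAs, which are shorter than the fragments of such libraries and are not described one by one. GC-adjusted, 5210 rose and 4349 fell; with quantile normalization 6029 rose and 3556 fell; among the 5920 genes under 48% GC 3622 rose and 921 fell. GC adjustment moved other named log2 fold changes: CDKN1A from -3.05 to -1.98, TFF1 from -4.62 to -3.82, HIST2H4A from -4.66 to -3.64, KRT19 from -4.03 to -2.52, JUP from -3.94 to -2.27 and RPL8 from -4.91 to -3.22. Scaled to the same total per library (TPM scale), where small RNA totals differ between replicates, 10 rose and 266 fell.

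**Figure D2:**
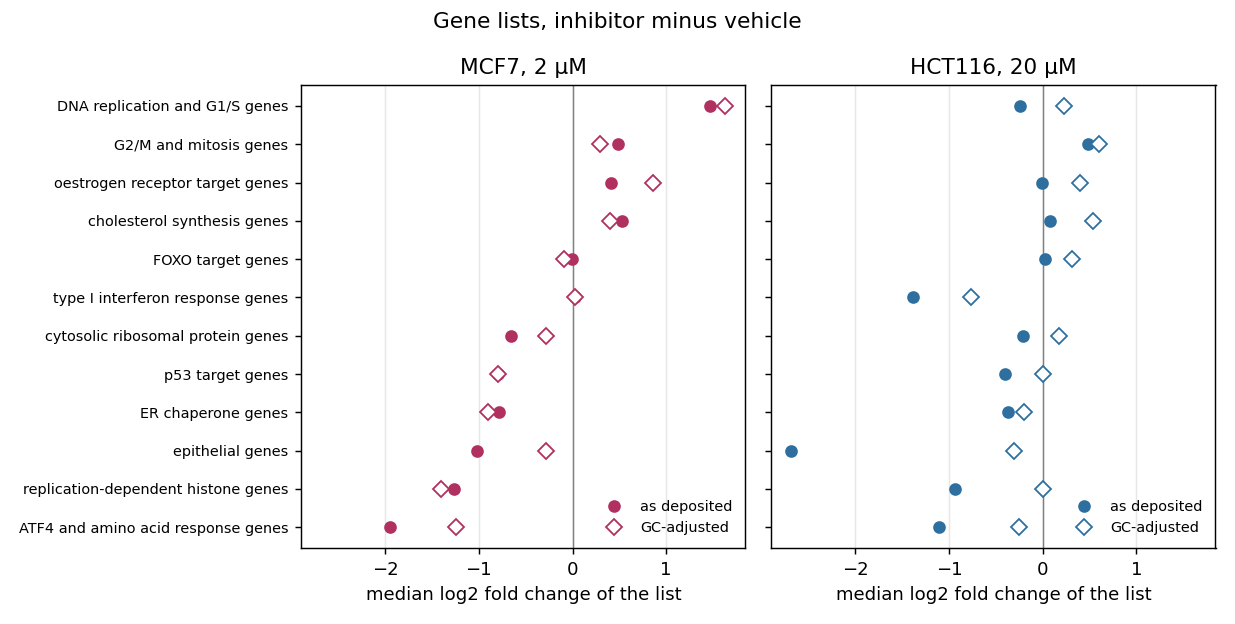
Median log2 fold change (inhibitor minus vehicle) of 12 gene lists in MCF7 at 2 µM (left) and HCT116 at 20 µM (right), from the values as deposited (filled circles) and after subtraction of the GC trend (open diamonds). DNA replication genes lie at 1.47 in MCF7 and -0.24 in HCT116, and type I interferon response genes at 0.03 and -1.38.

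The second comparison asked the same of HCT116 cells at 20 µM. G2/M and mitosis genes were higher with the inhibitor: of 36 measured, 29 rose and 5 fell, also when adjusted over the list alone, with a median of 0.48 (camera adjusted p = 4.59e-10, adjusted p = 0.319 with an estimated correlation). ANLN rose 2.02-fold from 11.6 ± 0.34 to 24.6 ± 0.297 FPKM (SD, n = 2 each; log2 fold change 1.02, SE 0.03, limma adjusted p = 6.48e-07), MKI67 1.66-fold, CCNB2 1.63-fold, TPX2 (a spindle assembly factor) 1.58-fold and DLGAP5 (a spindle protein) 1.54-fold. GC-adjusted, all 36 rose with a median of 0.60 (adjusted p = 3.2e-07). Relative to other genes, the DNA replication list did not pass the test: 8 rose and 20 fell, also when adjusted over the list alone (camera adjusted p = 0.789), while fry, which makes no comparison with other genes, called the list lower (adjusted p = 1.17e-05). The list median was -0.24, 0.36 with quantile normalization and 0.23 when GC-adjusted. MCM5, a helicase subunit with 56.6% GC, fell 34.6-fold (log2 fold change -5.11, -3.26 when GC-adjusted), while MCM2, with 58.1% GC, fell by 1.48 on the log2 scale and stood at 0.68 when GC-adjusted. CDC6 fell by 0.26 on the log2 scale, and stood at 0.21 with quantile normalization.

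Interferon response genes were lower in inhibitor-treated HCT116 cells. IFITM3, an antiviral membrane protein (chromosome 11, 319673 to 320914), fell from 602.9 ± 13.5 to 8.36 ± 1.27 FPKM (SD, n = 2 each; log2 fold change -6.02, SE 0.10, limma adjusted p = 2.5e-07; -4.29 when GC-adjusted). ISG15, a ubiquitin-like modifier, fell from 288.8 ± 51.6 to 0.224 ± 0.0248 FPKM and IRF9, a subunit of the interferon-activated transcription factor, from 25.4 ± 0.0396 to 5.43 ± 0.299 FPKM (SD, n = 2 each), with log2 fold changes of -7.88 and -2.04, or -4.30 and -0.53 when GC-adjusted. IFI27 was at 7.04 ± 0.456 FPKM (SD, n = 2) in vehicle and listed at 0 in both inhibitor libraries. Of 32 measured, 29 fell and 1 rose, or 30 and 1 when adjusted over the list alone, with a median of -1.38 (camera adjusted p = 0.000804, adjusted p = 0.319 with an estimated correlation, 0.0685 on the TPM scale, where the median was -1.43). GC-adjusted, 28 fell and 3 rose with a median of -0.76 (adjusted p = 7.59e-08).

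ATF4 targets also fell in HCT116: 22 of 27, with 2 rising, also when adjusted over the list alone (median -1.11, camera adjusted p = 0.0284, adjusted p = 0.823 with an estimated correlation). CHAC1, a glutathione-degrading enzyme with 62.6% GC, fell 86.3-fold and SLC7A5, an amino acid transporter with 61.1% GC, 28.5-fold. SLC7A11, with 35.4% GC, fell 1.20-fold and stood at 0.25 on the log2 scale with quantile normalization. ASNS rose 1.15-fold, and stood at -0.06 on the TPM scale. The list call ended when GC-adjusted (adjusted p = 0.146, median -0.25), on the TPM scale (0.666, median -1.35) and without HCT116 vehicle replicate 1 (0.0653). Of 24 epithelial genes 19 fell and 1 rose, also when adjusted over the list alone (median -2.68, camera adjusted p = 0.0488, adjusted p = 0.869 with an estimated correlation, 0.172 when GC-adjusted). KRT19 fell 73.7-fold and JUP 66.3-fold, and the call was lost without HCT116 vehicle replicate 1 (adjusted p = 0.0653) or without MCF7 vehicle replicate 1 (0.0554) or 2 (0.0545).

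Of 34 PI3K-AKT-mTOR pathway members in HCT116, 12 rose and 18 fell, also when adjusted over the list alone (median -0.20, camera adjusted p = 0.789, adjusted p = 0.916 with an estimated correlation; GC-adjusted median 0.02). IRS2 rose 3.03-fold, from 5.21 ± 0.295 to 17.8 ± 0.339 FPKM (SD, n = 2 each; limma adjusted p = 1.26e-06). Its transcript has 58.7% GC, and its log2 fold change was 1.60, or 4.07 when GC-adjusted. AKT1 fell 16.8-fold (log2 fold change -4.07, -1.77 when GC-adjusted) and AKT2 12.8-fold (-3.68, -1.34 when GC-adjusted). IGF1R rose by 0.18 on the log2 scale and INSR by 0.15, and these stood at -0.01 and -0.07 on the TPM scale; IGF1R stood at 0.89 when GC-adjusted. HES1, a Notch target (log2 fold change -0.06, adjusted p = 0.178), and ERBB3 (-0.08, adjusted p = 0.18) did not pass the test, and GC-adjusted they stood at 0.39 and 0.66. CDKN1B fell by 0.28 on the log2 scale (adjusted p = 0.0309), stood at 0.33 with quantile normalization and at -0.09 when GC-adjusted (0.424), and lost the call without any 1 of the 4 HCT116 libraries. Of 28 FOXO targets 12 rose and 10 fell, also when adjusted over the list alone (median 0.03, camera adjusted p = 0.054, adjusted p = 0.604 with an estimated correlation). The list did not pass when GC-adjusted (camera adjusted p = 0.489, median 0.31) or under 48% GC (0.526, median 0.22). The FOXO list passed, upward, with median-of-ratios scaling (adjusted p = 0.0496, median 0.23), with scaling to the total without small RNAs (0.0283, median 0.37) and without replicate 2 of either HCT116 group. Of 33 secreted growth and survival factor genes 24 fell and 1 rose, also when adjusted over the list alone (median -0.97, camera adjusted p = 0.054; GC-adjusted 14 rose and 15 fell, 0.489; it passed in 8 other settings, with adjusted p of 0.0304 to 0.0496). EREG (epiregulin, a ligand of EGFR) fell 1.96-fold from 411 ± 0.946 to 209.8 ± 3.92 FPKM (SD, n = 2 each) and VEGFA, the angiogenic growth factor, 3.07-fold. IGFBP3, an IGF-binding protein, fell 7.03-fold.

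In HCT116, 2834 genes rose and 6630 fell (limma adjusted p under 0.05), and 96 rose and 3889 fell at least 2-fold. CPA4, a secreted carboxypeptidase, rose 4.21-fold, and MIF, a secreted cytokine with 66.7% GC, fell from 869.5 ± 358 to 1.03 ± 0.968 FPKM (SD, n = 2 each). GC adjustment moved MIF from -8.76 to -4.18 on the log2 scale, CHAC1 from -6.43 to -2.94, SLC7A5 from -4.83 to -2.03, KRT19 from -6.20 to -3.22, JUP from -6.05 to -2.76, VEGFA from -1.62 to -0.98 and ASNS from 0.20 to 0.79. The balance followed the scaling: 4885 rose and 5523 fell with median-of-ratios scaling, 7618 and 3663 with quantile normalization, 5934 and 5486 with scaling to the total without small RNAs, and 19 and 2384 on the TPM scale. GC-adjusted, 5707 rose and 3679 fell. Of 9241 calls with a GC value 5912 kept their direction after adjustment and 2116 turned. Among genes under 48% GC, 2392 rose and 1281 fell. The median log2 fold change of all genes was -0.003 in MCF7 and -0.18 in HCT116, and moved to 0.182 and 0.509 with quantile normalization, -0.169 and -0.367 on the TPM scale and -0.042 and -0.001 with median-of-ratios scaling, so small changes in HCT116 are relative to these.

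The next comparison asked how much the responses of the lines had in common. SCD (stearoyl-CoA desaturase, which makes monounsaturated fatty acids) rose 2.50-fold in MCF7, from 351 ± 1.78 to 877 ± 14.0 FPKM, and 3.4-fold in HCT116, from 214 ± 1.85 to 731 ± 7.9 FPKM (SD, n = 2 each). CAV1 rose 14.9-fold and 2.66-fold, DKK1, a secreted Wnt antagonist, 3.43-fold and 3.37-fold, FAM122B 2.98-fold and 3.81-fold, and CAMK2N1, an inhibitor of CaM kinase II, 2.27-fold and 2.38-fold (log2 fold changes 1.19 and 1.25, or 1.51 and 2.09 when GC-adjusted). EIF4EBP1, the translation repressor that mTORC1 inactivates, fell 76.0-fold and 152-fold, SF3B5 (a splicing factor subunit) 106-fold and 111-fold and UBE2S (a ubiquitin-conjugating enzyme of mitosis) 56.4-fold and 65.2-fold. GC-adjusted, EIF4EBP1 stood at -4.18 and -2.94, SF3B5 at -5.82 and -4.97 and UBE2S at -4.99 and -4.39 on the log2 scale. Both lines called 1908 genes higher, where independent lists of these sizes would share 1042, and 4028 lower, where they would share 2458 (odds ratios 5.22 and 10.7, one-sided Fisher's exact test over genes, which are not independent). A further 1355 genes were called in opposite directions. The fold changes correlated with Pearson's r = 0.642 and Spearman's rho = 0.646 across genes. GC-adjusted, 3304 genes rose in both (2389 if independent), 2095 fell in both (1285) and 2129 were called in opposite directions. Pearson's r was then 0.541 and Spearman's rho 0.443. Under 48% GC 1688 rose in both (1463), 384 fell in both (199) and 846 were called in opposite directions. There r was 0.312 and rho 0.21. The lines have separate vehicle libraries.

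The last comparison tested whether the effects differed between the lines at their own doses, as the MCF7 effect minus the HCT116 effect. All 36 DNA replication genes had a higher effect in MCF7, also when adjusted over the list alone, with a median difference of 2.28 (camera adjusted p = 1e-07, adjusted p = 0.147 with an estimated correlation). CDC6 differed by 2.61 (SE 0.05), DTL, a ubiquitin ligase subunit of S phase, by 2.4, and MCM2 by 2.80 (limma adjusted p = 2.82e-06, 2.82e-06 and 3.55e-06). GC-adjusted, 35 of 36 remained higher with a median of 1.77 (camera adjusted p = 1.85e-15). Interferon response genes had a higher effect in MCF7 in 29 of 32 cases and a lower one in 0, or 30 and 0 when adjusted over the list alone (median 1.10, camera adjusted p = 0.000543, adjusted p = 0.155 with an estimated correlation; 26 of 32 and adjusted p = 2.78e-07 when GC-adjusted). ATF4 targets had a lower effect in MCF7 in 16 of 27 and a higher one in 7, also when adjusted over the list alone (median -0.46, camera adjusted p = 1.79e-07, adjusted p = 0.147 with an estimated correlation, 0.261 and median -0.63 with quantile normalization, 0.0558 and median -0.50 on the TPM scale; median -1.13 and adjusted p = 0.000566 when GC-adjusted). ASNS differed by -2.72 (SE 0.05) and SLC7A11 by -2.53 (SE 0.05). CCND1, which rose 2.72-fold in MCF7, fell by 0.68 on the log2 scale in HCT116 but stood there at 0.41 when GC-adjusted. EGR1, an immediate early transcription factor, rose by 2.08 in MCF7 (2.74 when GC-adjusted), fell by 1.09 in HCT116 and stood at 0.34 there when GC-adjusted.

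In this test 7913 genes had a higher and 1693 a lower effect in MCF7 (limma adjusted p under 0.05). The balance turned to 3955 and 4925 when GC-adjusted and to 3582 and 5431 with quantile normalization, and was 5851 and 3362 with median-of-ratios scaling, 5836 and 3776 with scaling to the total without small RNAs, 3095 and 1158 under 48% GC, and 419 and 18 on the TPM scale. MALAT1, a nuclear long non-coding RNA, fell 2.31-fold in MCF7 and rose 2.97-fold in HCT116, from 125 ± 2.14 to 374 ± 8.67 FPKM (SD, n = 2 each).

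**Figure D3:**
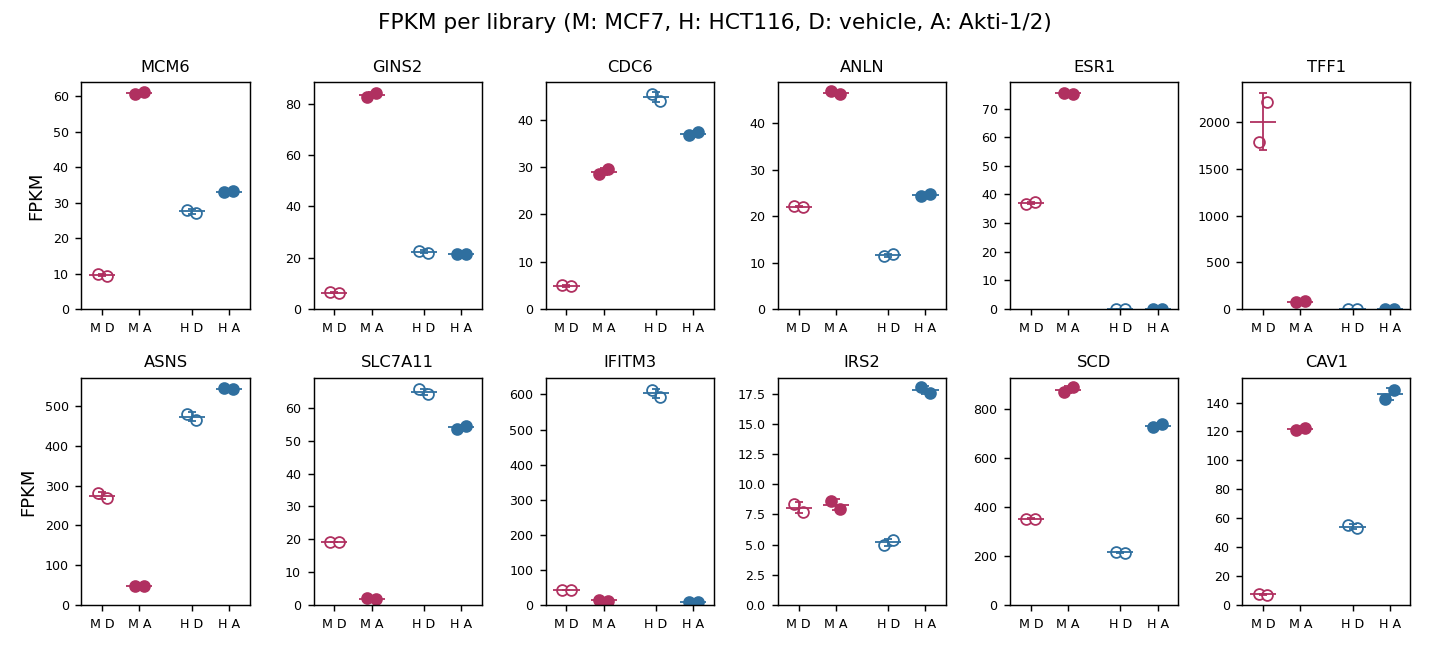
FPKM of 12 genes in each of the 8 libraries (M, MCF7; H, HCT116; D, vehicle, open circles; A, inhibitor, filled circles), with the mean as a horizontal line and the SD of 2 libraries as bars. GINS2 lies at 6.41 and 83.3 FPKM in MCF7 vehicle and inhibitor libraries, and ASNS at 275 and 47.2.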

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

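The tests of GC content, gene length, response to the inhibitor and nutrient state in this part were chosen after the results were seen; the test for a mislabelled library was written before. Results are listed here because the test of the difference between the lines (MCF7 effect minus HCT116 effect) passed its threshold. For gene lists, the camera adjusted p was 1e-07 for DNA replication and G1/S genes, 0.000543 for type I interferon response genes and 0.0218 for glycolysis genes, all toward a higher effect in MCF7. Toward a lower effect relative to other genes it was 1.79e-07 for ATF4 targets, 6.55e-06 for p53 targets, 1.58e-05 for cytosolic ribosomal protein genes, 6.02e-05 for ER chaperones, 0.000365 for FOXO targets, 0.000369 for replication-dependent histones and 0.00105 for G2/M genes. Some of these medians lay close to 0 or apart from their means: 0.03 and -0.01 for G2/M genes, -0.22 and 0.16 for p53 targets, -0.24 and 0.23 for ribosomal protein genes. With an estimated correlation none of the 10 passed, and when GC-adjusted the ribosomal protein call ended (adjusted p = 0.592, median -0.38). Under 48% GC the ribosomal protein list kept its call, with 1 of 20 genes higher and 11 lower. Its median there was -0.76 (camera adjusted p = 5.76e-05, adjusted p = 0.37 with an estimated correlation). Further lost calls are given with the processing.

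Among named genes, the difference was positive for CST6 (a cystatin, 5.28), EGR1 (3.17), MCM2 (2.80), CDC6 (2.61), CAV1 (2.49), DTL (2.396) and CCND1 (2.13). It was negative for KCNE4 (a potassium channel subunit, -3.39), CLGN (an ER chaperone, -3.26), FAM129A (Niban, -2.90), MALAT1 (-2.78), ASNS (-2.72), SLC7A11 (-2.53) and IRS2 (-1.56). These genes kept the sign of the difference when GC-adjusted, but several sizes moved: CST6 to 2.81, EGR1 to 2.41, MCM2 to 1.73, CCND1 to 1.47 and IRS2 to -2.75. CST6 was at 0 FPKM in all MCF7 libraries and KCNE4 at 0.0147 and 0.0151 FPKM in the HCT116 groups. As deposited, their differences are thus the change in the other line alone. The GC-adjusted CST6 difference also holds a value of 1.06 in MCF7, made by the adjustment, beside -1.75 in HCT116. Line and dose change together in this test, so neither can be named as the source of a difference.

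GC-rich genes fell in both lines. Gene length was argued against: its partial Spearman correlation with fold change, given GC, lay no further from 0 than -0.062. GC-dependent recovery of fragments could account for the trend. Genes of a single assembly split by GC content: within the ribosomal protein list Spearman's rho of fold change with GC was -0.68 in MCF7 and -0.70 in HCT116. This split repeats the trend over all genes in a subset of them, so it cannot single out a cause. A response of the cells to the inhibitor cannot be told apart from fragment recovery, because every inhibitor library differs from every vehicle library of its line in this trend. The vehicle libraries of the lines, which share a treatment, also differed from each other along GC (rho = -0.282). Per library, the median deviation from the gene mean was compared between the 1245 genes richest in GC and the genes in the lower part of the GC range. This log2 gap was 0.03 and 0.19 in MCF7 vehicle and 1.94 and 2.21 in HCT116 vehicle libraries. It was -1.15 to -1.07 in the inhibitor libraries of both lines, so the larger fall in HCT116 went with its vehicle libraries.

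DNA replication genes rose in MCF7. GC content as the whole cause was argued against by a GC-adjusted list median of 1.63. A single mislabelled library within MCF7 was argued against by 36 of 36 genes with both inhibitor libraries on the same side of both vehicle libraries; this says nothing on an exchange of both pairs of labels. That exchange, and a preparation or sequencing batch that goes with treatment, were not tested. A difference in culture state stays open: amino acid response genes were lower in inhibitor cells (GC-adjusted median -1.24), so vehicle cultures may have had less amino acid left at 72 h, which cannot be told apart from an effect of the inhibitor because culture age, cell density and treatment go together.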

How the results depend on the processing

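The settings on GC content, on small RNAs and on a common replicate block in this part were chosen after the results were seen; the others were written before the data were examined. Over these planned settings, the named gene values stayed on their side of the threshold 2612 times, turned weaker 112 times, stronger 4 times and reversed 12 times. List results were the same 423 times, weaker 49, stronger 51 and reversed 1 time. Of the gene values that turned weaker, 96 did so on the TPM scale, where each library is divided by its total, which differs between replicates through small RNAs. The cause of the other changes was not tested. No depth is known, so its limits cannot be given.

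A limit of 2-fold left 2630 genes changed in MCF7, 3985 in HCT116, 3421 in the line difference and 1886 changed alike in both lines, by construction. On the TPM scale these were 276, 2403, 437 and 212. Under 48% GC, where fewer genes are tested, they were 4543, 3673, 4253 and 2072, and with the replicate block 4771, 4005, 4552 and 2292. Leaving out each library in turn gave 8806 to 9707 genes in MCF7, 8656 to 9317 in HCT116, 8889 to 9258 in the line difference and 5415 to 5801 alike. Splits of the genes changed alike into rising and falling moved, from 1908 and 4028, when GC-adjusted (3304 and 2095), under 48% GC (1688 and 384), with a 2-fold limit (17 and 1869), with median-of-ratios scaling (2909 and 3879), quantile normalization (5226 and 2533), scaling to the total without small RNAs (3587 and 3819) and the TPM scale (2 and 210). The replicate block alone moved no count by over 1.5 times, and changed no call of a list or named gene but CDKN1B in MCF7.

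The correlation of log2 fold changes between lines, 0.642, was 0.685 with a pseudocount of 0.1, 0.624 on the TPM scale, 0.541 when GC-adjusted with or without the replicate block, 0.312 under 48% GC with or without that block, 0.740 without small RNAs and 0.658 with scaling to the total without small RNAs. It was 0.6 to 0.644 when each library was left out.

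In place of 4 lists past the threshold in HCT116, there were 9 without an FPKM filter, 7 with median-of-ratios scaling, 11 with quantile normalization, 2 on the TPM scale, 2 when GC-adjusted with or without the replicate block, 9 under 48% GC with or without that block, and 8 with scaling to the total without small RNAs. Leaving out a library gave 2 (without HCT116 vehicle replicate 1) to 9 (without HCT116 inhibitor replicate 2) in HCT116, 8 to 9 in MCF7 and 10 to 11 in the line difference. On the TPM scale 3 of the 10 lists of the line difference remained. With an estimated correlation 0 lists passed in MCF7, 0 in HCT116 and 0 in the line difference, while fry called 29, 35 and 33. Epithelial genes in HCT116 reversed under 48% GC (5 genes, median 0.05, camera adjusted p = 0.855, and 0.864 with the replicate block), and ribosomal protein genes in the line difference with quantile normalization (0.339). For the latter only the direction relative to other genes turned, since the list median was -0.32 against -0.24. The glycolysis list lost its call in the line difference without HCT116 vehicle replicate 1 (adjusted p = 0.0507). Other lost calls of the line difference were histones with a pseudocount of 0.1 (0.0627), with quantile normalization (0.101, where the median of -0.82 was larger in size than -0.42), with scaling to the total without small RNAs (0.182, median -0.44) and under 48% GC (0.237, median -0.32), and ER chaperones with quantile normalization (0.339, median -0.65 against -0.28). FOXO targets (0.132, median 0.06), G2/M genes (0.126, median 0.03) and glycolysis genes (0.754, median 0.22) lost theirs under 48% GC, where fewer of their genes were tested. On the TPM scale the calls lost were FOXO targets (0.14, median -0.10 against -0.02), G2/M genes (0.0867, -0.05 against 0.03), p53 targets (0.35, -0.29 against -0.22), glycolysis genes (0.285, 1.11 against 1.20), ribosomal protein genes (0.114, -0.30 against -0.24), ATF4 targets (0.0558, -0.50 against -0.46) and ER chaperones (0.225, -0.33 against -0.28), so these medians moved by at most 0.09. With fry, G2/M genes (0.329) and ribosomal protein genes (0.115) did not pass.

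These reversals cover the values the text gives for HCT116, and only INSR for MCF7. Log2 fold changes in HCT116 that reversed on the TPM scale were ASNS (-0.06), IGF1R (-0.01) and INSR (-0.07). With quantile normalization these were CDC6 (0.21), CDKN1B (0.33), CLGN (0.17), ERBB3 (0.58), HES1 (0.50) and SLC7A11 (0.25), and in MCF7 INSR (0.13). With scaling to the total without small RNAs they were CDC6 (0.11), CDKN1B (0.09), ERBB3 (0.29), HES1 (0.32) and SLC7A11 (0.12), and with median-of-ratios scaling ERBB3 (0.15) and HES1 (0.17). When GC-adjusted, with or without the replicate block, they were CCND1 (0.41), EGR1 (0.34), ERBB3 (0.66), HES1 (0.39) and MCM2 (0.68).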

Other observations

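The tests of shared reads reported in this part were chosen after the result was seen. The GC test was written before that result, but it uses the GC adjustment, which was added after the data were seen. Some genes of sterol synthesis rose. SQLE (squalene epoxidase) rose from 45.0 ± 0.603 to 119.7 ± 0.24 FPKM in MCF7 (SD, n = 2 each). INSIG1, a sterol-regulated protein of the ER, rose 2.20-fold in MCF7 and 3.48-fold in HCT116. TMEM97 rose 3.12-fold in MCF7, and STARD4, a sterol carrier, 2.27-fold in HCT116. Of all 26 cholesterol synthesis genes 15 rose and 10 fell in MCF7 (camera adjusted p = 0.17) and 12 rose and 12 fell in HCT116 (0.111). The HCT116 median of this list was 0.08, and -0.15 on the TPM scale. Of its 11 genes under 48% GC, 11 rose in MCF7 (median 1.07, camera adjusted p = 0.00748, 0.623 with an estimated correlation) and 10 rose and 0 fell in HCT116 (0.58, 0.000186, 0.518 with an estimated correlation), a limit chosen after the data were seen.

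Luminal breast markers in MCF7 included AGR2 and AGR3, proteins of the disulfide isomerase family, which rose 3.17-fold to 1027 ± 1.15 FPKM (SD, n = 2) and 4.29-fold, beside KRT19, which fell. Of 21 measured 13 rose and 6 fell (camera adjusted p = 0.156). Among secreted factors in MCF7, TGFB2 (transforming growth factor beta 2) rose 3.4-fold and the chemokine CXCL12 2.45-fold, while VEGFA fell from 65.9 ± 3.48 to 5.27 ± 0.182 FPKM (SD, n = 2 each). HES1 rose 1.81-fold in MCF7. CYP1A1, a target of the aryl hydrocarbon receptor, fell from 2.99 ± 0.325 to 0.411 ± 0.115 FPKM in MCF7 (SD, n = 2 each).

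Replicate 2 libraries shared a deviation from replicate 1 in all 4 groups. Of 30 genes over 2-fold apart in the same direction in all groups, 27 were higher in replicate 2, and 12 (40.0%) were annotated pseudogenes against 162 of 11508 tested (1.4%; ratio 28.4, Fisher's exact two-sided p = 2.79e-15). Reads shared between paralogs or pseudogenes could account for it; NACA2, chosen after its values were seen, was at 1.7 and 56.8 FPKM in replicates 1 and 2 of inhibitor-treated MCF7 cells and at 0.7 and 22.1 in vehicle-treated HCT116 cells. GC content was argued against, since 98.3% of the median difference was kept after GC adjustment. No biological explanation was tested.

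Small RNAs (names spanning less than 200 bp) summed to 90092 and 1784407 FPKM in replicates 1 and 2 of MCF7 inhibitor libraries, 176195 and 769081 of MCF7 vehicle, 153078 and 2204685 of HCT116 inhibitor and 129880 and 1054910 of HCT116 vehicle libraries. All other genes summed to between 333017 and 491178. EEF1A1, a translation elongation factor chosen after its values were seen, was at 6180 and 6480 FPKM in MCF7 inhibitor libraries and at 5683 in replicate 1 of HCT116 vehicle, and was listed at 0 in the other 5, where the status HIDATA in place of OK marks a locus with too many fragments to be quantified, so it was not tested.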
